A study of Mus musculus with 27 samples.

How the data were processed

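Single-nucleus RNA was measured with the 10x 3' v3.1 chemistry in hippocampus of 27 mice, 1 library each. The deposited matrices hold UMI counts per gene and nucleus barcode, 1 matrix per library with no normalization. The authors made them with Cell Ranger 6.1.2 on mm10, per the file headers and the submitters' notes. All 27 matrices carry the same 32285 mouse genes, and the lowest UMI count of a barcode was 500. Groups follow the labels on sex, APOE genotype, P301S tau and R47H, in 9 groups of 3. The labels give animals no shared numbers across groups, so no pairs were used. Gene positions come from GENCODE M21 on GRCm38, which is mm10, and human alleles have no features of their own.

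The 214966 barcodes (4894 to 10932 per library) were filtered to nuclei with at least 300 genes (333 removed) and under 5% mitochondrial counts (3451 removed). Scrublet in scanpy 1.11.5 scored doublets per library, and the highest scores were removed at 0.8% per 1000 nuclei, 13678 in all (3.84% to 8.61% per library). In all 197633 nuclei were kept, 4607 to 9836 per library. Counts scaled to 10000 per nucleus were log-transformed, and 3000 variable genes (dispersion within 20 bins of the mean per library, median rank over libraries) without mitochondrial genes, Xist, Tsix, 4 Y-linked genes, Trem2, Prnp, Apoe or Mapt gave 30 principal components. Leiden clustering (igraph 0.11.9, 15 neighbours, resolution 1) was run on all libraries together without batch integration.

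Clusters were named from 18 marker lists. A name needed 4 markers found in over 10% of nuclei at over 2-fold, a mean log2 fold of at least 1 over the other nuclei and a margin of 0.5 over the next list, with no more markers of another class among the 10 leading genes. It also needed 20 nuclei, and 1 cluster of low UMI count with no marker among its leading genes (310 nuclei, led by Tnfrsf12a and the senescence gene Cdkn1a) got no name. These limits were set after the clusters were seen. Of 41 clusters 24 were named, and 17 with 55467 nuclei (28.1%) were left out of every class. Classes held 13972 microglia, 22138 astrocytes, 36334 oligodendrocytes, 5325 oligodendrocyte precursors, 20516 DG, 12503 CA1 and 6670 CA3 neurons, 12994 inhibitory neurons and 756 T cells. T cells aside, the fewest nuclei in a library were 37 CA1 neurons (minimum 20).

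Raw counts were summed per library and class and fitted with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr by group, estimateDisp, robust glmQLFit on 9 group means over all 27 libraries, and glmQLFTest per contrast with Benjamini-Hochberg adjustment over the genes tested at 0.05. Contrasts were P301S against non-transgenic, R47H against wild-type TREM2 among P301S mice, and APOE4 against APOE3 among females, each within 3 strata and as a mean over the strata. Interactions, coded as APOE4 minus APOE3 or female minus male, and F_E4_P301S_R47H against F_E3_P301S were tested in microglia. Other classes were tested for the 3 means. SE is the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic, and CPM are computed from the summed counts. For 3 libraries against 3 an exact test of 1 value cannot go below 0.1, so genes rest on the shared dispersion. On simulated counts the microglia fit recovered 67% of genes changed 1.5-fold and 93% of genes changed 2-fold in a mean over strata. In the R47H comparison of APOE3 females it recovered 26% and 62%. The share of false calls was 2.44% to 8.33% over 4 simulated results. Pairs of replicates were checked for duplicated libraries, and none of 27 pairs of a group was one (chi-square per degree of freedom 11.4 or more).

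Shares of nuclei (pseudocount 0.5) were compared by an exact two-sided permutation test of the mean log2 difference over 3 strata, with adjustment over 16 classes and 3 factors. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists and contrasts of a class, for lists with at least 5 tested genes. Microglia lists were homeostatic and disease-associated microglia, type I interferon response, cGAS-STING sensing, NF-kB and cytokines, antigen presentation, senescence, lysosome and phagocytosis, lipid handling, cell cycle, immediate early and heat shock, unfolded protein response, nuclear-encoded respiratory chain and mitochondrially encoded genes, with markers of neurons, oligodendrocytes, astrocytes and border macrophages. Other classes added reactive and homeostatic astrocytes, disease-associated oligodendrocytes and myelin, and synaptic vesicle, glutamate receptor and ion channel genes. The lists are general knowledge and were not chosen on these samples.

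Named genes followed 1 rule: with adjusted p under 0.05, a mean of at least 20 CPM and groups that do not overlap (or the same sign in 3 strata), the 8 largest rises and 8 largest falls (6 and 6 outside microglia, 5 and 5 for interactions), up to 4 members of each list with the smallest adjusted p, and Trem2, Apoe, Mapt, Prnp, Cgas, Tmem173, Cdkn1a and Cdkn2a as targets. From these the text names a part, by preference those whose call held under the alternatives, a choice made after the values were seen, and some genes that met the rule are not reported here. The comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, except for some tests of explanations, named as such where they stand, and 2 alternatives, depth as a covariate (log10 of the median UMI count per nucleus of the class) and leaving out F_E3_P301S_R47H replicate 3, which gave 41.8% of the nuclei of a low-quality cluster. The other alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no low-count filter, age as a covariate, only the compared groups in the fit, a stricter nucleus filter (500 genes, 1% mitochondrial counts, doublet score under 0.15) and each replicate left out. Other splits of the samples were all 10 for 3 libraries against 3, and 40 drawn with a fixed seed for the rest. Cdkn2a was below the low-count filter in every class, and T cell markers had enough measured genes for a list test in DG neurons alone (adjusted p = 0.389 for P301S, adjusted p = 0.169 for R47H and adjusted p = 0.56 for APOE). Reads and human transgene sequences were not analysed here.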

Results

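Hippocampal nuclei of 27 mice were profiled by droplet-based RNA sequencing, with 1 library per mouse. All mice were homozygous for human APOE3 or human APOE4, the alleles with ordinary and raised risk of late-onset Alzheimer's disease. Of the mice, 18 carried P301S, a human tau transgene with a mutation of inherited frontotemporal dementia, driven by mouse Prnp sequence. Of those, 9 also carried 1 knock-in allele of human TREM2 with R47H, a risk variant in a lipid receptor of microglia. The 18 females made 6 groups of 3: non-transgenic, P301S and P301S R47H mice on APOE3 (F_E3_NTG, F_E3_P301S, F_E3_P301S_R47H) and on APOE4 (F_E4_NTG, F_E4_P301S, F_E4_P301S_R47H). The 9 males were all APOE4 and made the same 3 groups (M_E4_NTG, M_E4_P301S, M_E4_P301S_R47H). Ages were 9.2 to 10.1 months, apart from F_E3_NTG replicate 3 at 13.1 months. Libraries held 39532252 to 92303036 UMIs in all, and 197633 nuclei were kept. The median UMI count per kept nucleus was 3897.5 to 12292.5 over female libraries and 2725 to 5188.5 over male libraries, so that depth and sex went together. The series title concerns risk alleles for Alzheimer's disease, microglial senescence tied to the DNA sensor cGAS and loss of neurons under tau pathology. The comparisons addressed P301S tau per background, R47H among P301S mice and APOE4 against APOE3 among females, first in microglia, then in 7 other classes. No sequence of the human transgenes was among the 32285 features, so Apoe, Trem2 and Mapt counts are reads assigned to the mouse genes. Gene values below are log2 fold changes from edgeR ± SE derived from its F statistic, unless a unit is given. Adjusted p values are from edgeR or, for gene lists, from limma's camera.

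Prnp and sex-linked genes separated the libraries as labelled, and Trem2 did so among P301S mice. In microglia, Trem2 (chromosome 17, 48346401 to 48354147, mm10) stood at 219.8 ± 34.8 CPM (SD, n = 9) in R47H mice. It stood at 409.6 ± 89.6 CPM (n = 9) in P301S mice with wild-type TREM2 and at 349 ± 97.8 CPM (n = 9) in non-transgenic mice, whose range the R47H libraries overlapped. Over all nuclei Prnp, the prion protein gene, was at 112 ± 14.5 CPM in the 18 P301S libraries and 71.9 ± 6.7 CPM in the 9 others, with no overlap. Mapt, the tau gene, was at 498 ± 41.7 and 427 ± 52.9 CPM, and its ranges overlapped. Apoe reads were at 32.4 to 62.4 CPM in APOE3 and 21.3 to 106 CPM in APOE4 libraries and so did not check the APOE label. Xist, which silences 1 X chromosome in females, and the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y put all 27 libraries in their stated sex.

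P301S mice had higher shares of microglia, astrocyte and T cell nuclei and lower shares of the named DG and CA1 neuron classes among all nuclei. T cell nuclei took a 6.2-fold higher share in P301S than in non-transgenic mice, from 0.111% ± 0.0217 (SD, n = 3) in M_E4_NTG to 0.944% ± 0.307 in M_E4_P301S. Microglia rose 1.88-fold and astrocytes 1.72-fold, and all 3 shares were higher in each of the 3 strata (female APOE3, female APOE4, male APOE4). Dentate gyrus granule neurons (DG) fell to 0.398 of their non-transgenic share, and CA1 pyramidal neurons to 0.392. Both falls were steepest by fold in males, where DG neurons went from 19.0% ± 1.27 to 2.56% ± 0.768 and CA1 neurons from 10.1% ± 0.607 to 2.13% ± 2.5; differences between strata were not tested. In the female strata the DG ratios were 0.606 and 0.795, and those of CA1 were 0.508 and 0.927. An exact permutation test stratified by background (8000 relabellings, two-sided, 48 tests) gave adjusted p = 0.006 for T cells, microglia, astrocytes and DG neurons, and adjusted p = 0.0456 for CA1, where the smallest raw p the relabellings can give is 0.00025. By the same exact test CA3 neurons (0.498-fold, adjusted p = 0.0514), oligodendrocytes (1.16-fold, 0.0514) and mural cells (1.95-fold, 0.0525) did not pass. No share passed for R47H or for APOE4, with adjusted p of 0.588 or more and 0.184 or more. By the exact test the CA1 call was lost without F_E3_P301S replicate 2 (adjusted p = 0.0528) or F_E3_NTG replicates 2 (0.0624) or 3 (0.0514). It was also lost without F_E4_NTG replicate 1 (0.06), F_E4_P301S replicate 2 (0.0984) or M_E4_NTG replicates 1 (0.174), 2 (0.167) or 3 (0.167). CA3 neurons passed without F_E3_P301S replicate 3 (0.0394), F_E4_NTG replicate 2 (0.028) or F_E4_P301S replicate 3 (0.0096). Against neuron nuclei alone, DG changed by -0.53 on the log2 scale (exact test, adjusted p = 0.11) and CA1 by -0.55 (0.465). Against the named non-neuronal classes alone the log2 rise shrank from 2.63 to 2.16 for T cells (adjusted p = 0.012), from 0.91 to 0.43 for microglia (0.012) and from 0.78 to 0.31 for astrocytes (0.044). Astrocytes held a cluster led by Myoc, A2m, Gfap and C3 that made 0.742% to 0.803% of nuclei in the 3 non-transgenic groups and 3.75% to 10.9% in the P301S groups, so the astrocyte class drew on different clusters. Clusters given no class made 23.5% to 35.0% of nuclei per group, and those as deep as neurons went both ways, which was not tested. With P301S, 1 of them (median 10450 UMIs) went from 0.305% to 3.35% of nuclei in APOE3 females, from 2.73% to 2.82% in APOE4 females and from 1.87% to 6.53% in males. Another (13532 UMIs) went from 2.8% to 1.27%, from 3.03% to 1.11% and from 1.72% to 0.485% in the same order.

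**Figure D1:**
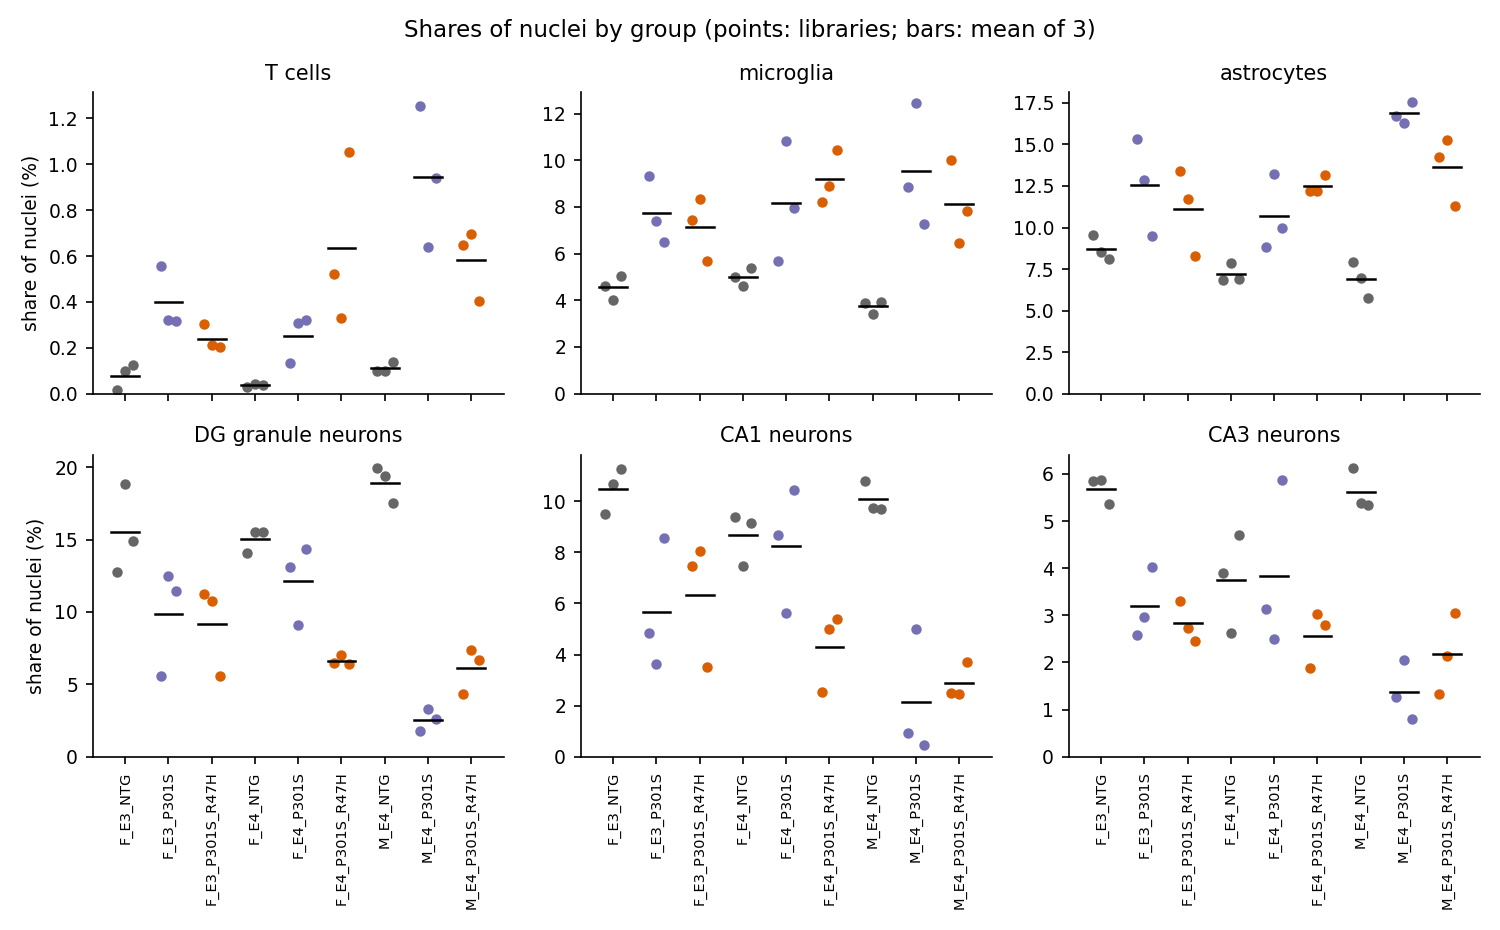
Shares of nuclei (percent of all kept nuclei, linear axis) for T cells, microglia, astrocytes and 3 classes of principal neurons in the 9 groups, with 1 point per library and a bar at the mean of 3. Grey marks non-transgenic, purple P301S and orange P301S R47H groups. DG points lie lowest in M_E4_P301S, at 1.78% to 3.31%.

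In microglia, P301S tau came with lower expression of the genes of resting microglia and higher expression of disease-associated and interferon genes. Over the mean of the 3 strata (9 P301S against 9 non-transgenic mice), 28 of the 30 measured homeostatic genes fell and 0 rose (28 fell adjusted over the list alone), with a median of -0.85. Among them were Tmem119, a marker of resident microglia (-1.27 ± 0.13), Sparc (-0.95 ± 0.09), the adhesion receptor gene Adgrg1 (-1.11 ± 0.12) and Lrba (-0.90 ± 0.08). Of 40 disease-associated genes, 38 rose and 0 fell (38 rose adjusted over the list alone), with a median of 2.29. Axl, a receptor for dying cells, rose by 5.52 ± 0.40, the osteopontin gene Spp1 by 6.40 ± 0.87, the sialic acid lectin gene Cd22 by 2.83 ± 0.27 and Arhgap24 by 1.92 ± 0.15. Gpnmb, a glycoprotein gene of lipid-laden phagocytes, had no counts in any non-transgenic group and was at least 42.9-fold higher in P301S mice, with 3 counts over each group of 3 libraries as the floor. Of 55 type I interferon response genes, 50 rose and 0 fell (51 rose adjusted over the list alone). They included the DNA-binding Ifi204 (4.07 ± 0.39), the class I transactivator Nlrc5 (3.18 ± 0.21) and the double-stranded RNA kinase Eif2ak2 (1.23 ± 0.14). Among the largest changes outside these lists were the heparanase gene Hpse (46.0 against 0.153 CPM, means of 9 libraries each) and Aoah, a lipopolysaccharide hydrolase gene (50.3 against 1.04 CPM). Sema4b (-2.70 ± 0.24), the clock-related factor gene Hlf (-2.28 ± 0.19), Myo18b (-2.55 ± 0.24) and the interleukin-7 receptor gene Il7r (-2.32 ± 0.28) were among the largest falls. In all, 1543 genes rose and 1098 fell of 12311 tested. camera gave adjusted p = 2.77e-35, and adjusted p = 0.0063 with an estimated correlation, for the homeostatic list. It gave adjusted p = 6.2e-67, and adjusted p = 0.0063 with an estimated correlation, for the disease-associated list. For the interferon list it gave adjusted p = 1.92e-42, and adjusted p = 0.0896 with an estimated correlation. The interferon median was 1.99, or 1.87 with 11 members that had a group at 0 set to their bound. The class included a small cluster led by Ifi204 and Cxcl10, at 0.0609% to 0.187% of all nuclei in P301S groups and at most 0.00462% in non-transgenic groups, so its mix differed too. With depth as a covariate, chosen after seeing that depth differed between groups, 1314 genes passed in place of 2641.

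**Figure D2:**
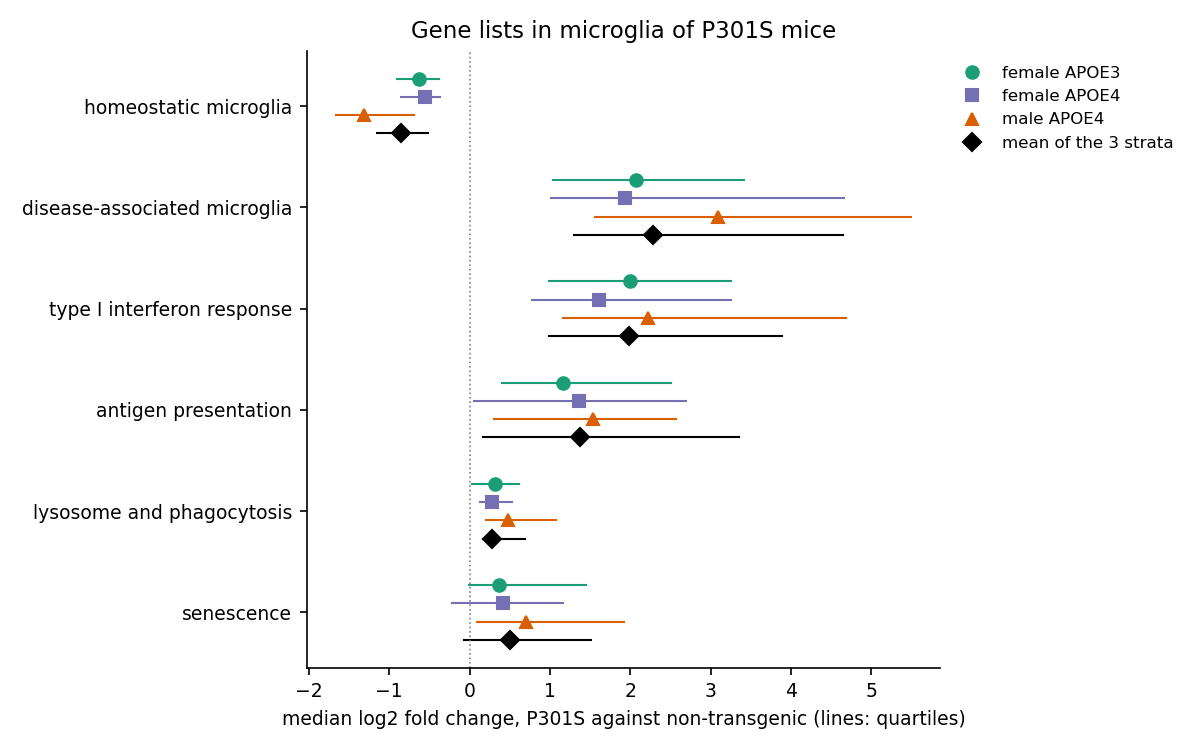
Median log2 fold change in microglia (horizontal axis) for 6 fixed gene lists, P301S against non-transgenic mice, as 1 point per stratum and a diamond for their mean. Lines run from the lower to the upper quartile of the genes of the list. Disease-associated and interferon medians lie above 0 and homeostatic medians below 0 in all 3 strata.

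The genes around the cGAS-STING pathway moved in both directions in P301S microglia. Cgas itself, the sensor of cytosolic DNA, had a log2 change of 0.29 ± 0.13, adjusted p = 0.108, and did not pass. Its call was gained without F_E3_P301S replicate 1 (adjusted p = 0.0437), in a range of 0.0437 to 0.601 over 26 alternatives. Tmem173, which encodes STING, fell (-0.75 ± 0.14, adjusted p = 1.02e-04), while Enpp1, an ectoenzyme that degrades cGAMP, rose by 2.38 ± 0.28 and the kinase gene Ikbke stood at 44.9 against 0.786 CPM (means of 9 libraries; adjusted p = 3.23e-05). Of 18 members of that list, 5 rose and 1 fell (6 and 1 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.21). Of 62 senescence genes, 30 rose and 6 fell (30 and 9 adjusted over the list alone; adjusted p = 2.6e-08, and adjusted p = 0.0063 with an estimated correlation). Its rising members Axl, Ctsb (1.13 ± 0.11) and Timp2 (1.05 ± 0.12) also stand in the disease-associated list, and Plaur, the urokinase receptor gene, rose by 2.69 ± 0.28. Cdkn1a, the p21 inhibitor gene, was at 1.35 ± 0.50, adjusted p = 0.0488. Its call was lost with age as a covariate (adjusted p = 0.0771), with depth as a covariate (0.0883), with F_E3_P301S_R47H replicate 3 out of the fit (0.0512), with a stricter nucleus filter (0.0592), with only the compared groups in the fit (0.0791), without F_E3_P301S replicates 2 (0.065) and 3 (0.0887), without F_E3_NTG replicates 2 (0.0937) and 3 (0.103), without F_E4_NTG replicates 1 (0.0963) and 3 (0.0948), without F_E4_P301S replicates 2 (0.0654) and 3 (0.0694), without M_E4_NTG replicates 1 (0.0928) and 2 (0.0792) and without M_E4_P301S replicates 1 (0.0831) and 2 (0.0539), at log2 changes of 1.16 to 1.73, in a range of 0.00357 to 0.103 over 26 alternatives. NF-kB and cytokine genes rose in 18 of 33 cases and fell in 1 (20 and 3 adjusted over the list alone; adjusted p = 1.06e-05, and adjusted p = 0.0686 with an estimated correlation). The chemokine gene Ccl3 rose by 2.86 ± 0.44, and Il6 was the 1 that fell (-1.77 ± 0.26). Antigen presentation genes rose in 16 of 25 cases (17 adjusted over the list alone; adjusted p = 1.02e-12, and adjusted p = 0.115 with an estimated correlation). B2m (1.37 ± 0.11) and H2-D1 (2.22 ± 0.22) were among them. For lysosome genes 26 of 48 rose and 2 fell (29 and 3 adjusted over the list alone; adjusted p = 1.11e-09, and adjusted p = 0.113 with an estimated correlation). Atp6v1b2, a proton pump subunit gene, rose by 0.87 ± 0.09. For lipid genes 13 of 30 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 3.02e-05, and adjusted p = 0.0943 with an estimated correlation). The sterol esterification gene Soat1 rose by 1.13 ± 0.11. Apoe reads rose by 2.48 ± 0.41. Mitochondrially encoded genes fell in 10 of 12 cases (10 adjusted over the list alone; adjusted p = 4.14e-08, and adjusted p = 0.115 with an estimated correlation). Of 14 cell cycle genes 4 rose (4 adjusted over the list alone; adjusted p = 0.044, and adjusted p = 0.425 with an estimated correlation). The immediate early list (20 genes, 4 up, 1 down; 4 and 4 adjusted over the list alone) did not pass (adjusted p = 0.934) and had a median of -0.17 against a mean of 0.10. The unfolded protein list (30 genes, 5 up, 11 down; 5 and 12 adjusted over the list alone) did not pass either (adjusted p = 0.208; median -0.16, mean 0.03, tested direction down). Nuclear respiratory chain genes did not pass as a list (adjusted p = 0.32; 1 of 40 rose and 1 fell, 0 and 0 adjusted over the list alone). Nor did markers of neurons (adjusted p = 0.0576; 3 of 19 fell, 2 adjusted over the list alone), oligodendrocytes (adjusted p = 0.133; 2 of 13 rose, 2 over the list alone), astrocytes (adjusted p = 0.389; of 9, 1 rose and 1 fell, 1 and 1 over the list alone) or border macrophages (adjusted p = 0.691; of 5, 1 rose and 1 fell, 1 and 1 over the list alone).

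Each background showed the microglial response to P301S on its own. In APOE3 females 378 genes rose and 171 fell, among them Axl (5.17 ± 0.65), the vascular growth factor receptor gene Flt1 (4.23 ± 0.74), Bcar3 (5.28 ± 0.88) and Ifi207 (4.98 ± 0.94) upward, and the adenylyl cyclase gene Adcy8 (-1.90 ± 0.29), Sema4b (-1.94 ± 0.35) and Nhs (-3.27 ± 0.55) downward. In APOE4 females 271 rose and 133 fell, with the cystatin gene Cst7 at 5.14 ± 0.98, Ifi204 at 3.91 ± 0.67, Sema4b at -2.29 ± 0.37 and Hlf at -1.89 ± 0.36. In APOE4 males 1009 rose and 732 fell: the galectin gene Lgals3 rose by 6.25 ± 0.75, Enpp1 by 4.23 ± 0.57 and Soat1 by 1.85 ± 0.22, the purine oxidase gene Xdh was at least 42.5-fold higher, and Selplg (-2.01 ± 0.24), Myo18b (-3.80 ± 0.48) and Kcnk12 (-3.24 ± 0.37) fell. Homeostatic genes fell in 17, 7 and 27 of 30 cases in the 3 strata in that order (23, 24 and 27 adjusted over the list alone), and disease-associated genes rose in 21, 25 and 36 of 40 (33, 33 and 38 adjusted over the list alone). Both lists passed in all 3 strata with an estimated correlation, at adjusted p = 0.0129, 0.0166 and 0.0063 and adjusted p = 0.00832, 0.00832 and 0.00637. Interferon genes rose in 21, 11 and 32 of 55 (48, 33 and 44 adjusted over the list alone), with adjusted p = 0.0686, 0.115 and 0.196 with an estimated correlation. In males 11 of 12 mitochondrially encoded genes fell (12 adjusted over the list alone), as with mt-Co1 (-1.52 ± 0.18). camera gave adjusted p = 6.65e-21, and 0.00929 with an estimated correlation. The source of this RNA was not tested.

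Few genes passed for a different P301S response of microglia between backgrounds or sexes (3 mice per group), while gene lists differed between sexes. No gene's P301S response differed between APOE backgrounds by the edgeR interaction test (382 at an unadjusted p under 0.05 and 0 by DESeq2). Between sexes 1 gene differed, mt-Co1, with a female minus male difference of 1.43 ± 0.25, adjusted p = 0.0307. Its call was lost with age as a covariate (adjusted p = 0.0535), with depth as a covariate (0.801), with a stricter nucleus filter (0.15), without F_E4_NTG replicates 2 (0.146) and 3 (0.187), without F_E4_P301S replicates 1 (0.141) and 3 (0.183), without M_E4_NTG replicates 1 (0.205) and 3 (0.131) and without M_E4_P301S replicate 3 (0.155), at log2 changes of 1.17 to 1.42, in a range of 3.09e-06 to 0.801 over 20 alternatives. DESeq2 called 36 genes. The mitochondrially encoded list differed, with a median female minus male difference of 1.46 (1 of 12 passed alone, 10 adjusted over the list alone; adjusted p = 9.02e-25, and adjusted p = 0.0063 with an estimated correlation). The homeostatic (0.54) and disease-associated lists (-0.76) and neuronal markers (0.44) differed at the preset correlation alone (adjusted p = 2.63e-04 or less, and 0.0566 or more with an estimated correlation). The count of genes for the difference by sex was 0 and 0 without F_E4_NTG replicates 2 and 3 and 0, 33 and 0 without F_E4_P301S replicates 1, 2 and 3. It was 0 and 0 without M_E4_NTG replicates 1 and 3 and 4, 2 and 0 without M_E4_P301S replicates 1, 2 and 3. Male microglia also differed in depth, with a median UMI count of 1062 ± 188 per nucleus in M_E4_NTG and 1973 ± 319 in M_E4_P301S (SD, n = 3), and with depth as a covariate 307 genes passed in males in place of 1741. The count of 549 in APOE3 females became 274 with age as a covariate and 323 without F_E3_P301S replicate 2 and 292 and 304 without F_E3_NTG replicates 2 and 3. That of 404 in APOE4 females became 152, 156 and 175 without F_E4_NTG replicates 1, 2 and 3 and 686, 53 and 123 without F_E4_P301S replicates 1, 2 and 3. That of 1741 in males became 1098 without M_E4_NTG replicate 3.

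Mouse Trem2 was lower in R47H microglia, where 1 allele is human, so it checks the label. No other gene passed in the mean over 3 P301S strata by edgeR. Trem2 changed by -0.90 ± 0.12 (adjusted p = 0.00197). It was lower in each stratum (-0.81 ± 0.21, -1.08 ± 0.21 and -0.82 ± 0.22) and passed in none by edgeR. The Trem2 call was gained with no low-count filter (adjusted p = 6.98e-05), in a range of 6.98e-05 to 1 over 13 alternatives, in APOE3 females. In APOE4 females it was gained with no low-count filter (adjusted p = 1.33e-09), with only the compared groups in the fit (0.0476) and by DESeq2 (0.0236), in a range of 1.33e-09 to 1 over 14 alternatives, and in males it was gained with no low-count filter (adjusted p = 3.72e-06) and by DESeq2 (0.0418), in a range of 3.72e-06 to 0.513 over 14 alternatives. Cgas (0.03 ± 0.11, adjusted p = 1) and Tmem173 (-0.06 ± 0.13, adjusted p = 0.997) did not pass. An unadjusted p under 0.05 was found for 659 genes, and DESeq2 called 1. In APOE3 and APOE4 females edgeR called 0 and 0 genes, with 316 and 555 at an unadjusted p under 0.05 and 0 and 2 by DESeq2. The APOE4 count became 4 without F_E4_P301S replicate 2. In APOE4 males 5 genes were higher and 23 lower with R47H, among them Siglech, a homeostatic lectin gene (1.06 ± 0.21), upward and Lgals3, a disease-associated galectin gene (-1.63 ± 0.31), downward. With depth as a covariate no gene passed there, and median depth was 1424 ± 105 UMIs in M_E4_P301S_R47H against 1973 ± 319 in M_E4_P301S (SD, n = 3). The count of 28 became 0, 138 and 8 without M_E4_P301S replicates 1, 2 and 3 and 14, 1 and 1 without M_E4_P301S_R47H replicates 1, 2 and 3. The Siglech call was lost with depth as a covariate (adjusted p = 0.374), with only the compared groups in the fit (0.239), without M_E4_P301S replicates 1 (0.2) and 3 (0.129) and without M_E4_P301S_R47H replicates 2 (0.156) and 3 (0.0786), at log2 changes of 0.75 to 1.16, in a range of 6.9e-11 to 0.374 over 14 alternatives. The Lgals3 call was lost with depth as a covariate (adjusted p = 0.501), with only the compared groups in the fit (0.164), without M_E4_P301S replicates 1 (0.153) and 3 (0.0596) and without M_E4_P301S_R47H replicates 1 (0.0613), 2 (0.0593) and 3 (0.145), at log2 changes of -1.85 to -1.05, in a range of 1.06e-07 to 0.501 over 14 alternatives. Disease-associated genes leaned down in males (median -0.76; 3 of 40 fell, 18 adjusted over the list alone; adjusted p = 2.35e-25, and adjusted p = 0.0627 with an estimated correlation). Homeostatic genes leaned up (median 0.36; 1 of 30 rose, 7 adjusted over the list alone; adjusted p = 1.06e-11, and adjusted p = 0.0896 with an estimated correlation). Mitochondrially encoded genes stood higher (1 of 12 rose, 12 adjusted over the list alone; adjusted p = 3.77e-21, and adjusted p = 0.0097 with an estimated correlation). Senescence genes stood lower (1 of 62 fell and 0 rose, 6 and 1 adjusted over the list alone; adjusted p = 3.62e-07, and adjusted p = 0.0063 with an estimated correlation). Neuronal marker RNA was higher in the same microglia (median 0.55; adjusted p = 5.27e-07, and adjusted p = 0.351 with an estimated correlation). In APOE4 females the homeostatic list leaned the other way (median -0.31; 0 fell, 2 adjusted over the list alone; adjusted p = 1.09e-11, and adjusted p = 0.0901 with an estimated correlation). The interferon list leaned down in APOE3 females (median -0.24; adjusted p = 4.54e-07, and adjusted p = 0.645 with an estimated correlation).

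The effect of R47H on homeostatic genes differed between the sexes as a list. The female minus male difference had a median of -0.62 (1 of 30 genes fell, 15 adjusted over the list alone; adjusted p = 2.67e-21, and adjusted p = 0.0166 with an estimated correlation). Markers of other cells differed in the same contrast, neuronal ones by -0.68 and those of border macrophages by 1.29 (adjusted p = 0.0335 or less, and 0.194 or more with an estimated correlation). So did mitochondrially encoded genes (-1.06; adjusted p = 5.05e-15, and adjusted p = 0.0275 with an estimated correlation), and the sexes differed in depth. 1 gene passed alone, the matrix protein gene Sparc (-1.25 ± 0.21, adjusted p = 0.017), whose R47H value was -0.73 ± 0.15 in females and 0.52 ± 0.15 in males. Neither passed alone. In females the call was gained with no low-count filter (adjusted p = 0.00106), by DESeq2 (0.0403) and without F_E4_P301S replicate 2 (0.028), in a range of 0.00106 to 1 over 14 alternatives, and in males it was gained without M_E4_P301S replicate 2 (adjusted p = 0.0249), in a range of 0.0249 to 0.606 over 14 alternatives. The call of the difference was lost with depth as a covariate (adjusted p = 0.842), with only the compared groups in the fit (0.204), without F_E4_P301S replicates 1 (0.121) and 3 (0.119), without F_E4_P301S_R47H replicates 2 (0.0674) and 3 (0.0999), without M_E4_P301S replicates 1 (0.144) and 3 (0.0713) and without M_E4_P301S_R47H replicate 2 (0.0633), at log2 changes of -1.27 to -0.99, in a range of 4.98e-06 to 0.842 over 20 alternatives. The count of 1 became 20 by DESeq2. It was 11, 0 and 0 without F_E4_P301S_R47H replicates 1, 2 and 3 and 0, 39 and 0 without F_E4_P301S replicates 1, 2 and 3. It was 0, 54 and 0 without M_E4_P301S replicates 1, 2 and 3 and 4 and 0 without M_E4_P301S_R47H replicates 1 and 2. DESeq2 size factors gave 1 gene higher and 1 lower. No gene's R47H effect differed between APOE backgrounds by edgeR (408 at an unadjusted p under 0.05, 0 by DESeq2). That count became 1 without F_E4_P301S_R47H replicate 1.

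APOE4 microglia differed from APOE3 microglia in 251 genes when the 3 female strata were averaged (9 against 9 mice). Pirb, an inhibitory receptor gene, was lower (-1.13 ± 0.20, adjusted p = 0.00412), as was the mitochondrial translation gene Taco1 (-0.89 ± 0.18, adjusted p = 0.00905), while the fatty acid desaturase gene Fads1 was higher (0.81 ± 0.17, adjusted p = 0.00905). In all 125 genes were higher and 126 lower of 12311 tested by edgeR. Lysosome genes had a median of 0.09 (2 of 48 rose, 3 adjusted over the list alone; adjusted p = 0.00391, and adjusted p = 0.554 with an estimated correlation). APOE3 female libraries were 1.45 times as deep as APOE4 ones in microglia (3053 against 2104 UMIs per nucleus). With depth as a covariate 1 gene passed, and the adjusted p was 0.821 for Pirb, 0.978 for Taco1 and 0.601 for Fads1, each the highest over 25 alternatives, whose lowest were 2.19e-08, 3.77e-05 and 1.99e-04. Their log2 changes were then -0.82, -0.20 and 1.04. The count of 251 became 139 with age as a covariate. It was 109 and 163 without F_E3_P301S_R47H replicates 1 and 2 and 153 without F_E3_P301S replicate 2. It was 97 without F_E3_NTG replicate 3 and 87 and 121 without F_E4_NTG replicates 1 and 2. It was 95 and 96 without F_E4_P301S_R47H replicates 2 and 3 and 106 without F_E4_P301S replicate 2. Within single strata edgeR called 0 genes in non-transgenic, 0 in P301S and 1 in P301S R47H females, with 1109, 1215 and 816 at an unadjusted p under 0.05 and 2, 27 and 2 by DESeq2. The 1 gene was Lilra5 (3.34 ± 0.53, adjusted p = 0.00396), a leukocyte receptor gene named here after its values were seen. The count for non-transgenic females became 1 without F_E4_NTG replicate 3. The count for R47H females became 2, 0 and 3 without F_E3_P301S_R47H replicates 1, 2 and 3 and 4 without F_E4_P301S_R47H replicate 1. The Lilra5 call was lost without F_E3_P301S_R47H replicate 2 (adjusted p = 0.171), at a log2 change of 3.09, in a range of 9.31e-09 to 0.171 over 13 alternatives. Mice with both risk alleles (F_E4_P301S_R47H) against F_E3_P301S gave 0 genes by edgeR (710 at an unadjusted p under 0.05, 1 by DESeq2). That count became 1 without F_E3_P301S replicate 1 and 1 without F_E4_P301S_R47H replicate 3. Cgas (0.23 ± 0.18, adjusted p = 0.895) and Trem2 (-0.71 ± 0.21, adjusted p = 0.85) did not pass there. The Trem2 call was gained with no low-count filter (adjusted p = 0.00101), in a range of 0.00101 to 1 over 14 alternatives.

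Astrocytes of P301S mice had higher expression of reactive astrocyte and interferon genes. Of 45 reactive astrocyte genes 36 rose and 0 fell (40 rose adjusted over the list alone), such as the complement inhibitor gene Serping1 (3.21 ± 0.27), the oncostatin receptor gene Osmr (2.62 ± 0.21), the complement gene C4b (1.58 ± 0.11) and Ggta1 (2.28 ± 0.18). Of 47 interferon genes 43 rose (45 adjusted over the list alone), with the chemokine Cxcl10 at 5.69 ± 0.95 and Nlrc5 at 3.29 ± 0.34. Their median was 2.19, or 1.88 with 6 members at their bound. Antigen presentation genes rose in 14 of 17 cases (14 adjusted over the list alone; adjusted p = 4e-12, and adjusted p = 0.0537 with an estimated correlation). Cdkn1a rose by 2.93 ± 0.61 and the death receptor gene Fas by 2.16 ± 0.22. Of 64 senescence genes 27 rose and 9 fell (34 and 10 adjusted over the list alone; adjusted p = 1.97e-06, and adjusted p = 0.0537 with an estimated correlation). Falling genes included Cyp51 (-1.58 ± 0.25), Msmo1 (-1.49 ± 0.18) and Idi1 (-1.74 ± 0.31), all enzymes of sterol synthesis, which had no list of its own. In all 13 of 36 lipid genes fell and 6 rose (14 and 6 adjusted over the list alone; adjusted p = 0.00145, and adjusted p = 0.201 with an estimated correlation). Of 29 homeostatic astrocyte genes 17 fell and 2 rose (19 and 3 adjusted over the list alone; adjusted p = 7.54e-08, and adjusted p = 0.149 with an estimated correlation). Among them was the transporter gene Slc7a10 (-0.60 ± 0.08). In total 1575 genes rose and 1140 fell of 14579 tested. camera gave adjusted p = 1.38e-57, and adjusted p = 0.00466 with an estimated correlation, for the reactive list. For the interferon list it gave adjusted p = 2.99e-47, and adjusted p = 0.0537 with an estimated correlation. With depth as a covariate 1448 genes passed in place of 2715.

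Oligodendrocytes and their precursors (OPC) had higher expression of interferon and disease-associated oligodendrocyte genes in P301S mice. In oligodendrocytes C4b rose by 3.32 ± 0.25, the protease inhibitor gene Serpina3n by 3.19 ± 0.34, the class I gene H2-D1 by 3.22 ± 0.36 and the kallikrein gene Klk6 by 2.22 ± 0.28. The disease-associated oligodendrocyte list rose in 18 of 31 genes (21 up and 1 down adjusted over the list alone; adjusted p = 3e-33, and adjusted p = 0.00344 with an estimated correlation). The interferon list rose in 23 of 29 genes (24 adjusted over the list alone; adjusted p = 3.73e-43, and adjusted p = 0.00586 with an estimated correlation). Antigen presentation rose in 12 of 14 (13 adjusted over the list alone; adjusted p = 7.52e-26, and adjusted p = 0.00589 with an estimated correlation). Of 30 myelin genes 0 rose and 1 fell (0 and 0 adjusted over the list alone; adjusted p = 0.0819). In oligodendrocytes 632 genes rose and 374 fell, in a class of 3 clusters whose mix differed between groups, with 1 at 0.166% of nuclei in M_E4_NTG and 2.73% in M_E4_P301S. The total of 1006 became 308 with depth as a covariate. It was 581 without F_E3_P301S replicate 1 and 636 without F_E4_P301S replicate 2. In OPC C4b rose by 4.15 ± 0.27, the RNA sensor gene Ifih1 by 3.32 ± 0.46, Ddx60 by 2.84 ± 0.48 and the tetraspanin gene Cd9 by 0.83 ± 0.15, while the growth factor gene Vegfa (-0.83 ± 0.15) and the lipid transporter gene Mfsd2a (-0.92 ± 0.15) fell. OPC interferon genes rose in 20 of 25 cases (21 adjusted over the list alone; adjusted p = 3.9e-51, and adjusted p = 0.00188 with an estimated correlation). Disease-associated oligodendrocyte genes rose in 8 of 18 (13 adjusted over the list alone; adjusted p = 1.13e-23, and adjusted p = 2.95e-04 with an estimated correlation). Myelin genes rose in 4 of 25 OPC cases (10 adjusted over the list alone; adjusted p = 9.58e-09, and adjusted p = 0.354 with an estimated correlation). In OPC 165 genes rose and 102 fell. Their total of 267 became 176 without F_E4_P301S replicate 2 and 161 without M_E4_NTG replicate 1. It was 173 and 453 without M_E4_P301S replicates 1 and 2.

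Interferon genes rose in principal neurons of P301S mice as well. In CA1 neurons 24 of 36 interferon genes rose (32 adjusted over the list alone; adjusted p = 5.73e-58, and adjusted p = 0.00787 with an estimated correlation). Among them were the helicase gene Ddx60 (5.68 ± 0.64), the ubiquitin ligase gene Trim25 (3.05 ± 0.46) and Xaf1 (2.23 ± 0.31). CA1 antigen presentation genes rose in 7 of 13 cases (11 adjusted over the list alone; adjusted p = 6.76e-14, and adjusted p = 0.00787 with an estimated correlation). The stress-linked transcription factor gene Jun (0.92 ± 0.17) and the cholesterol exporter gene Abca1 (0.80 ± 0.14) rose there, and the vesicular glutamate transporter gene Slc17a7 (-0.45 ± 0.09) and Myo5b (-0.97 ± 0.12) fell. In DG neurons 21 of 30 interferon genes rose (23 adjusted over the list alone; adjusted p = 7.72e-19, and adjusted p = 0.117 with an estimated correlation), with Irf7 at 2.79 ± 0.56. The protein folding genes Hspa5 (-0.72 ± 0.13) and Pdia4 (-0.93 ± 0.21) fell. They were among 6 falling of 31 unfolded protein genes (9 fell and 1 rose adjusted over the list alone; adjusted p = 0.00839, and adjusted p = 0.591 with an estimated correlation). Of 44 glutamate receptor genes in DG neurons 9 rose and 3 fell (9 and 3 adjusted over the list alone; adjusted p = 0.0536). Of 39 synaptic vesicle genes 2 rose and 3 fell (4 and 3 over the list alone; adjusted p = 0.17). Of 48 ion channel genes 6 rose (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.0143, and adjusted p = 0.591 with an estimated correlation). By edgeR 575 genes rose and 505 fell in DG, and 160 rose and 98 fell in CA1 neurons. The DG count of 1080 became 709 without M_E4_P301S replicate 3. That of 258 in CA1 became 150 and 444 without F_E3_P301S replicates 1 and 3 and 168 without F_E4_P301S replicate 2. It was 168 and 480 without M_E4_P301S replicates 1 and 2.

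In CA3 neurons the granin gene Vgf rose by 0.79 ± 0.12 and 7 of 26 interferon genes rose (13 adjusted over the list alone; adjusted p = 2.35e-10, and adjusted p = 0.19 with an estimated correlation). In inhibitory neurons the netrin receptor gene Unc5c, which lies within 5 Mb of Gm43049 (below), fell (-0.82 ± 0.07) and the class I gene H2-K1 rose (1.38 ± 0.22). Prnp, whose sequence drives the transgene, rose by 0.71 ± 0.06 in DG, 0.66 ± 0.07 in CA1, 0.92 ± 0.08 in CA3 and 0.65 ± 0.08 in inhibitory neurons. Gm43049, a long noncoding RNA gene (chromosome 3, 140692038 to 140760704), stood in the 18 P301S libraries at 41.5 ± 12.3 CPM (SD) in DG, 66.4 ± 21.1 in CA1, 58.7 ± 17.5 in CA3 and 52.2 ± 15.3 in inhibitory neurons. In the 9 non-transgenic libraries it stood at 0.0322, 0.0233, 0.0378 and 0.0531 CPM in the same order, and the difference passed in all 4 (adjusted p = 6.2e-10 or less). Genes higher and lower numbered 79 and 48 in CA3 and 32 and 8 in inhibitory neurons. Oligodendrocyte marker RNA was higher in P301S in all 4 classes, with medians of 0.44 (adjusted p = 0.00771, and adjusted p = 0.591 with an estimated correlation), 0.33 (adjusted p = 8.91e-04, and adjusted p = 0.356 with an estimated correlation), 0.51 (adjusted p = 2.89e-06, and adjusted p = 0.19 with an estimated correlation) and 0.36 (adjusted p = 1.57e-05, and adjusted p = 0.418 with an estimated correlation). The count of 127 in CA3 became 45 with depth and 58 with age as a covariate. It was 40, 76 and 216 without F_E3_P301S replicates 1, 2 and 3 and 53 and 71 without F_E3_NTG replicates 2 and 3. It was 56, 79 and 67 without F_E4_NTG replicates 1, 2 and 3 and 226, 58 and 58 without F_E4_P301S replicates 1, 2 and 3. It was 56 and 66 without M_E4_NTG replicates 1 and 3 and 65, 271 and 66 without M_E4_P301S replicates 1, 2 and 3. That of 40 in inhibitory neurons became 13, 26 and 119 without F_E3_P301S replicates 1, 2 and 3 and 76, 17 and 25 without F_E3_NTG replicates 1, 2 and 3. It was 21 and 17 without F_E4_NTG replicates 1 and 3 and 12 without F_E4_P301S replicate 2. It was 22, 103 and 10 without M_E4_NTG replicates 1, 2 and 3 and 227 and 23 without M_E4_P301S replicates 2 and 3.

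**Figure D3:**
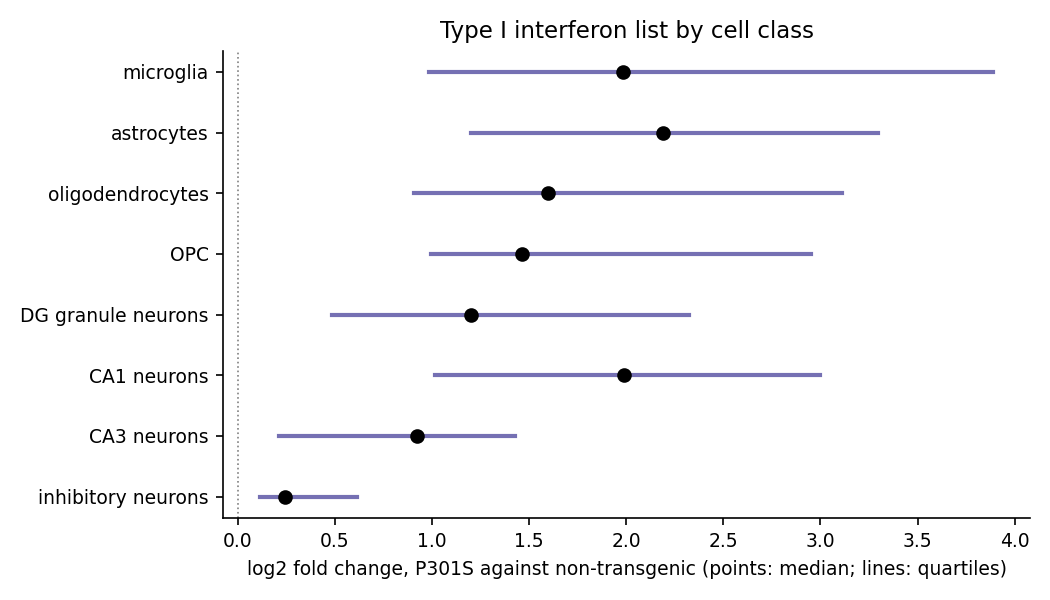
Median log2 fold change of the type I interferon list, P301S against non-transgenic mice, mean over 3 strata, in 8 cell classes (points; horizontal axis), with lines from the lower to the upper quartile of the genes measured. Medians run from 0.24 in inhibitory neurons to 2.19 in astrocytes.

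By edgeR with the low-count filter no gene passed for R47H in 7 other classes (mean over 3 strata). edgeR called 0 genes in each, with 749 genes at an unadjusted p under 0.05 in astrocytes, 403 in oligodendrocytes, 477 in OPC, 671 in DG, 1478 in CA1, 899 in CA3 and 733 in inhibitory neurons. DESeq2 called 0, 0, 0, 0, 67, 0 and 0 in the same order. Reactive astrocyte genes had a median of -0.26 with 0 rising and 0 falling (0 and 0 adjusted over the list alone; adjusted p = 3.49e-05, and adjusted p = 0.536 with an estimated correlation). In CA1 neurons ion channel genes had a median of 0.09 (0 of 48 rose, 11 adjusted over the list alone; adjusted p = 8.7e-09, and adjusted p = 0.151 with an estimated correlation). Glutamate receptor genes there had a median of 0.11 (0 of 44 rose, 6 adjusted over the list alone; adjusted p = 9.04e-07, and adjusted p = 0.227 with an estimated correlation). In inhibitory neurons mitochondrially encoded genes had a median of -0.28 (0 of 13 fell, 0 adjusted over the list alone; adjusted p = 2.04e-09, and adjusted p = 0.418 with an estimated correlation). In astrocytes the count of 0 became 1 without F_E4_P301S replicate 1 and 1 without M_E4_P301S_R47H replicate 3. In CA1 neurons it became 5 without F_E3_P301S replicate 1 and 2 without F_E4_P301S_R47H replicate 1. It was 28 without M_E4_P301S replicate 2 and 13 without M_E4_P301S_R47H replicate 2.

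APOE4 and APOE3 females differed at many genes in neurons, alongside a difference in depth. Averaged over 3 female strata, 1566 genes were higher and 1316 lower with APOE4 in inhibitory neurons, 1149 and 1053 in CA1, 1192 and 990 in DG, 583 and 498 in CA3, 427 and 479 in astrocytes, 425 and 408 in oligodendrocytes, and 142 and 97 in OPC. Apoe reads were higher in DG (0.55 ± 0.11, adjusted p = 0.00184) and inhibitory neurons (0.61 ± 0.11, adjusted p = 8.6e-04), and the cold-shock RNA-binding gene Cirbp in inhibitory neurons (0.65 ± 0.10, adjusted p = 2.18e-04). Gm17167, a gene on chromosome 4 (42206998 to 42235313), was lower in DG neurons (-7.41 ± 0.17, adjusted p = 2.18e-24). Over 8 classes its mean was 1.36 to 62.4 CPM in APOE3 and at most 0.359 in APOE4 libraries. In oligodendrocytes Taco1 (-1.18 ± 0.17, adjusted p = 5.1e-04) and the kinase gene Camk1d (-1.31 ± 0.20, adjusted p = 0.00333) were lower. Nuclear respiratory chain genes had a median of 0.24 in inhibitory neurons (18 of 40 rose, 22 rose and 1 fell adjusted over the list alone; adjusted p = 1.57e-08, and adjusted p = 0.418 with an estimated correlation). Ion channel genes there had one of -0.14 (11 of 48 fell and 4 rose, 19 and 4 adjusted over the list alone; adjusted p = 7.5e-04, and adjusted p = 0.523 with an estimated correlation). APOE3 female libraries were 1.38 to 1.54 times as deep per nucleus as APOE4 ones in these 7 classes. With depth as a covariate 4, 6, 4, 3, 2, 3 and 1 genes passed in the order given. Of the genes named here Gm17167 alone then passed, and the adjusted p was 0.987 and 0.841 for Apoe in DG and inhibitory neurons, 0.453 for Cirbp, 0.932 for Taco1 and 0.821 for Camk1d, each the highest over 25 alternatives, whose lowest were 1.11e-06, 5.85e-09, 3.69e-11, 4.15e-17 and 3.09e-51. Their log2 changes were then 0.04, 0.13, 0.40, -0.53 and -0.74. The CA1 count of 2202 became 1357 without F_E4_NTG replicate 1 and 1357 and 1197 without F_E4_P301S_R47H replicates 2 and 3. The DG count of 2182 became 1339 without F_E4_NTG replicate 1 and 1349 and 1394 without F_E4_P301S_R47H replicates 2 and 3. The CA3 count of 1081 became 709 and 626 without F_E3_P301S replicates 1 and 2 and 602 and 701 without F_E3_P301S_R47H replicates 1 and 3. It was 631 without F_E3_NTG replicate 3 and 1646, 438 and 434 without F_E4_P301S_R47H replicates 1, 2 and 3. It was 510 and 544 without F_E4_NTG replicates 1 and 2 and 656 and 687 without F_E4_P301S replicates 1 and 2. The astrocyte count of 906 became 483 without F_E3_P301S_R47H replicate 1 and 556 without F_E3_NTG replicate 2. It was 1360, 361 and 368 without F_E4_P301S_R47H replicates 1, 2 and 3 and 375 and 433 without F_E4_NTG replicates 1 and 2. It was 454 without F_E4_P301S replicate 2. The oligodendrocyte count of 833 became 297 without F_E3_P301S_R47H replicate 1 and 492 without F_E3_P301S replicate 2. It was 454 and 391 without F_E3_NTG replicates 2 and 3 and 244 and 396 without F_E4_NTG replicates 1 and 2. It was 492 and 449 without F_E4_P301S replicates 1 and 2 and 324 and 270 without F_E4_P301S_R47H replicates 2 and 3. The OPC count of 239 became 159 and 153 without F_E3_P301S replicates 1 and 2 and 138 without F_E3_P301S_R47H replicate 1. It was 145 and 135 without F_E3_NTG replicates 2 and 3 and 112 and 130 without F_E4_NTG replicates 1 and 2. It was 141 and 155 without F_E4_P301S replicates 1 and 2 and 100 without F_E4_P301S_R47H replicate 3.

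**Figure D4:**
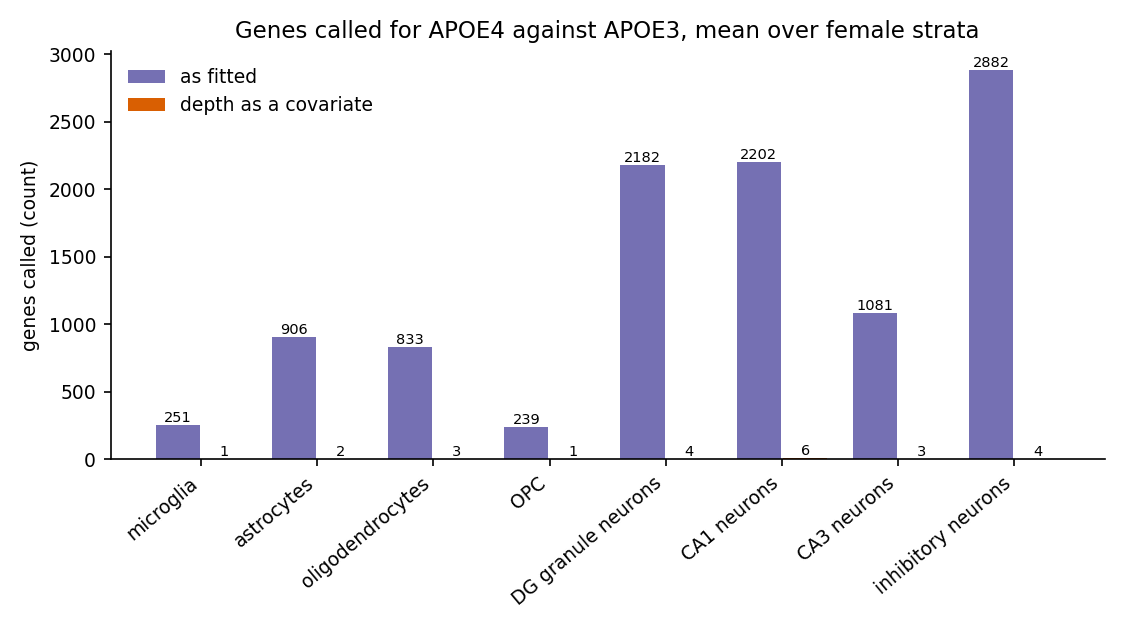
Genes called for APOE4 against APOE3 (count, linear axis) in 8 cell classes, as fitted and with the median UMI count per nucleus as a covariate. Counts of 239 to 2882 fall to 1 to 6 with the covariate.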

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

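Depth as a covariate was chosen only after the results of this part were seen. All results here are differences between groups. In microglia a test of the difference itself passed for 2 genes and for 25 of 72 gene list differences, and in 2 of 144 pairs of share differences the replicates of 1 group all moved up and those of the other all moved down. The P301S effect on mt-Co1 was -1.52 ± 0.18 in males, and that in APOE4 females minus that in males was 1.43. Under depth as a covariate it was 1.17 (adjusted p = 0.801). The R47H effect on Sparc differed between females and males by -1.25, and by -0.99 under depth as a covariate (adjusted p = 0.842).

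Female minus male medians of the P301S effect were 0.54 for homeostatic, -0.76 for disease-associated, -0.58 for interferon, -0.34 for senescence and -0.44 for lipid genes, 1.46 for mitochondrially encoded genes and 0.44 for neuronal markers. Female minus male medians of the R47H effect were -0.62 for homeostatic, 0.91 for disease-associated, 0.32 for interferon, 0.30 for cGAS-STING, 0.22 for senescence, 0.16 for lysosome and 0.49 for lipid genes. They were -1.06 for mitochondrially encoded genes, -0.68 for neuronal and 1.29 for border macrophage markers. Between APOE backgrounds (APOE4 minus APOE3), the medians of the P301S effect were -0.22 for interferon genes and 0.75 for neuronal markers. Those of the R47H effect were -0.25 for homeostatic, 0.41 for interferon, 0.23 for antigen presentation, -0.69 for cell cycle and 0.27 for immediate early genes and -0.41 for neuronal markers. All of these passed by camera at the preset correlation with adjusted p = 0.0335 or less, and 4 held with an estimated correlation: the P301S difference of mitochondrially encoded genes by sex (adjusted p = 0.0063), and the R47H differences by sex of homeostatic (adjusted p = 0.0166), senescence (adjusted p = 0.0259) and mitochondrially encoded genes (adjusted p = 0.0275). Fitted values of members with a group at 0 enter these medians, and a difference between effects has no bound for them.

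With R47H the share of DG granule neuron nuclei changed by -5.54 percentage points in APOE4 females and by 3.58 in males, a difference (female minus male) of -9.12 that was not tested. The T cell share changed by -0.158 points in APOE3 and by 0.383 in APOE4 females, a difference (here APOE3 minus APOE4) of -0.541 that was not tested either.

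Other splits were counted for the differences between effects, 40 for each. For P301S by sex, 7 of the 40 splits gave 1 gene or more, the real count, and the highest other gave 1840. For R47H by sex 6 of the 40 did, with a real count of 1 and a highest other of 28. For P301S and R47H by APOE the real count was 0, which all 40 splits reached, and the highest others were 840 and 0. Splits with 840 and 1840 genes may exchange libraries within 1 background (not tested) and so create differences. The splits thus cannot decide on chance.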

How the results depend on the processing

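Depth as a covariate and leaving out the low-quality library (F_E3_P301S_R47H replicate 3) were chosen after the data were seen; the other alternatives were not. No paired analysis was possible because each mouse has a number of its own in the labels, and replicate numbers here only follow the order of the samples. Genes whose call held were named by preference, so counts of kept calls describe the genes named and not genes in general. Of 124 gene results named in the texts, all kept their direction and their side of the threshold with DESeq2 size factors, 119 with no low-count filter (the other 5 gained a call), 121 by DESeq2 (3 gained), 122 with age and 122 with the stricter nucleus filter. Under depth as a covariate 111 did, and 13 lost their call in the same direction. With only the compared groups in the fit 117 of 122 did, 4 lost and 1 gained a call. Without the low-quality library, where its group was not compared, 109 of 110 did and 1 lost it. Over 1872 fits of those genes without 1 replicate, 1825 gave the same call and direction, 37 lost and 3 gained a call, and 7 changed sign. The sign changes were at values near 0 that passed no test, in the R47H effect averaged over strata in microglia. For Cgas, the log2 change was -0.0269 without F_E3_P301S replicate 1, -9.79e-04 without F_E3_P301S_R47H replicate 2, -0.0025 without F_E4_P301S replicate 3, -8.68e-04 without M_E4_P301S replicate 3 and -0.0247 without M_E4_P301S_R47H replicate 1. For Tmem173 it was 0.0136 without M_E4_P301S replicate 2 and 0.0341 without M_E4_P301S_R47H replicate 3. Over all fits without 1 replicate the values ran from -0.0269 to 0.0669 and from -0.138 to 0.0341. Of 243 list results, 202 lost their call with an estimated correlation, and 3 lost and 1 gained one with DESeq2 size factors. The 108 label gene values moved by less than the spread between replicates under the stricter filter.

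Counts of called genes moved by more than 1.5 times as follows, and the cause was not tested. With no low-count filter, counts for P301S went from 549 to 970 in microglia of APOE3 females, 404 to 757 in microglia of APOE4 females, 1006 to 1579 in oligodendrocytes, 267 to 490 in OPC, 1080 to 1792 in DG and 258 to 852 in CA1. Others went from 127 to 636 in CA3 and 40 to 572 in inhibitory neurons. Those for R47H went from 0 to 33 in microglia of APOE3 females, 0 to 37 in microglia of APOE4 females, 28 to 342 in microglia of males, 1 to 121 in microglia averaged over strata, 0 to 94 in astrocytes and 0 to 40 in oligodendrocytes. Others went from 0 to 1 in OPC, 0 to 30 in DG, 0 to 171 in CA1, 0 to 48 in CA3 and 0 to 27 in inhibitory neurons. Those for APOE went from 0 to 57 in microglia of non-transgenic females, 0 to 86 in microglia of P301S females, 1 to 76 in microglia of R47H females, 0 to 78 in microglia with both risk alleles and 251 to 406 in microglia averaged over strata. Those for interactions went from 0 to 31 for P301S by APOE, 0 to 26 for R47H by APOE, 1 to 127 for P301S by sex and 1 to 224 for R47H by sex. Under depth as a covariate, counts for P301S went from 1741 to 307 in microglia of males, 2641 to 1314 in microglia averaged over strata, 2715 to 1448 in astrocytes, 1006 to 308 in oligodendrocytes and 127 to 45 in CA3. Those for R47H went from 28 to 0 in microglia of males. Those for APOE went from 251 to 1 in microglia averaged over strata, 906 to 2 in astrocytes, 833 to 3 in oligodendrocytes, 239 to 1 in OPC, 2182 to 4 in DG and 2202 to 6 in CA1. Others went from 1081 to 3 in CA3 and 2882 to 4 in inhibitory neurons. Those for interactions went from 1 to 0 for P301S by sex and 1 to 0 for R47H by sex. With only the compared groups in the fit, counts for P301S went from 404 to 268 in microglia of APOE4 females and 40 to 21 in inhibitory neurons. Those for R47H went from 0 to 1 in microglia of APOE4 females and 28 to 11 in microglia of males. Those for APOE went from 0 to 2 in microglia of non-transgenic females, 0 to 3 in microglia of P301S females, 1 to 16 in microglia of R47H females, 0 to 1 in microglia with both risk alleles, 251 to 454 in microglia averaged over strata and 906 to 1379 in astrocytes. Others went from 833 to 1353 in oligodendrocytes and 239 to 397 in OPC. Those for interactions went from 1 to 0 for R47H by sex. By the DESeq2 Wald test, counts for P301S went from 127 to 213 in CA3 and 40 to 110 in inhibitory neurons. Those for R47H went from 0 to 2 in microglia of APOE4 females, 28 to 61 in microglia of males and 0 to 67 in CA1. Those for APOE went from 0 to 2 in microglia of non-transgenic females, 0 to 27 in microglia of P301S females, 1 to 2 in microglia of R47H females, 0 to 1 in microglia with both risk alleles and 251 to 413 in microglia averaged over strata. Those for interactions went from 1 to 36 for P301S by sex and 1 to 20 for R47H by sex. With age as a covariate, counts for P301S went from 549 to 274 in microglia of APOE3 females, 127 to 58 in CA3 and 40 to 24 in inhibitory neurons. Those for APOE went from 251 to 139 in microglia averaged over strata and 833 to 543 in oligodendrocytes. Those for interactions went from 1 to 0 for P301S by sex and 1 to 2 for R47H by sex. With the stricter nucleus filter, counts for interactions went from 1 to 0 for P301S by sex and 1 to 5 for R47H by sex. With DESeq2 size factors, counts for interactions went from 1 to 2 for R47H by sex. Without the low-quality library, counts for interactions went from 1 to 3 for R47H by sex. For R47H by sex, 0% of the calls were higher in females as fitted and 50% with DESeq2 size factors.

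Without 1 replicate at a time, counts for P301S ran from 292 to 601 in microglia of APOE3 females, 53 to 686 in microglia of APOE4 females, 1098 to 1830 in microglia of males, 581 to 1402 in oligodendrocytes and 161 to 453 in OPC. Further ones ran from 709 to 1548 in DG, 150 to 480 in CA1, 40 to 271 in CA3 and 10 to 227 in inhibitory neurons. Those for R47H ran from 0 to 4 in microglia of APOE4 females, 0 to 138 in microglia of males, 0 to 1 in astrocytes and 0 to 28 in CA1. Those for APOE ran from 0 to 1 in microglia of non-transgenic females, 0 to 4 in microglia of R47H females, 0 to 1 in microglia with both risk alleles, 87 to 374 in microglia averaged over strata and 361 to 1360 in astrocytes. Further ones ran from 244 to 1248 in oligodendrocytes, 100 to 325 in OPC, 1339 to 2743 in DG, 1197 to 2860 in CA1 and 434 to 1646 in CA3. Those for interactions ran from 0 to 1 for R47H by APOE, 0 to 33 for P301S by sex and 0 to 54 for R47H by sex. Where leaving out a replicate leaves 2 libraries in a group, these are taken to vary like the other groups. Shares of nuclei passed or failed the same way in 97 of 108 such tests. The log2 change of the CA1 share ran from -1.67 to -1.11 and lost its call in 8 of them, and that of the CA3 share ran from -1.12 to -0.89 and gained one in 3. Against the named neuron classes alone, of which both are part, the DG share (-0.53) and the CA1 share (-0.55) no longer passed. In the R47H comparison of APOE3 females (3 against 3 libraries) the fit recovered 26% of genes simulated at a 1.5-fold change, and 69% in the mean over strata, so effects of R47H below that in 1 stratum would mostly not be detected.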

Other observations

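The tests of a window around Apoe, of free RNA shared by all nuclei and of Gm43049 were chosen only after the result was seen. P301S mice showed further changes in single genes, with no shared theme tested, and each call here held under every alternative run. In astrocytes the heparan sulfatase gene Sulf1 rose by 3.58 ± 0.29. In oligodendrocytes the complement protease gene Masp1 rose by 2.57 ± 0.23 and the class I light chain gene B2m by 2.44 ± 0.36.

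The rise of the interferon list in CA1 neurons (summed CPM) was set against free RNA as its source. It was 105, 116 and 355 in the 3 strata (P301S SD 4.7, 85.1 and 272, n = 3). At the marker levels in CA1 nuclei, RNA of microglia would bring 15.4, 10.5 and 25.6 CPM. The rise was at least 6.82 times that and 11.1 times what astrocytes would bring. The rise in inhibitory neurons was at most 0.255 of that in CA1 neurons, where RNA shared by all nuclei would raise both alike. These means argue against the 3 sources, most clearly in APOE3 females. A CA1 response may underlie the rise, a hypothesis found and tested on the same data. Free RNA of oligodendrocytes, whose markers rose in CA1 nuclei, and doublets with glia beyond the filter were not tested.

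Calls for APOE in neurons may reflect depth as well as genotype, since APOE3 females were sequenced more deeply. Once depth was a covariate, 0.139% of the calls were left in inhibitory and 0.273% in CA1 neurons: the median size of the log2 fold change of the called genes went from 0.34 to 0.17 and from 0.36 to 0.19, and the median SE from 0.0912 to 0.132 and from 0.094 to 0.133, so calls ended through smaller folds and wider errors. With each library's trend on gene length as a covariate 6.7% of the inhibitory calls were left (median size 0.18, SE 0.11) and 15.9% of the CA1 calls (median size 0.24, SE 0.102), which lies between the limits set for CA1, so there the trend and genotype cannot be told apart. Microglia calls were not clearly more frequent within 20 Mb of Apoe (Fisher's exact test, odds ratio 1.73, 95% interval 0.808 to 3.28), an interval too wide to tell a strain variant there from none; odds ratios elsewhere were 1.08 to 1.84, with intervals above 1 in oligodendrocytes, DG and CA3 neurons. In that window 133 genes were called in any class and 77 in 2 or more, 76 of these in 1 direction. The same was not counted elsewhere. Depth and APOE genotype go together here, so an effect of APOE4 itself stays open and was not tested apart from depth.

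Gm43049 was weighed because it rose in every neuron class of P301S mice from nearly no counts. Its rise over that of Prnp was 0.972 to 1.9 in the 5 classes where both passed, a span of 1.96 times, just under the 2 times allowed for counts taken from transcripts of the transgene alone; in oligodendrocytes (0.473) and microglia (0.146), where Prnp did not pass, it was lower, and in astrocytes, where it did not pass either, it was 1.11. Other genes within 5 Mb were called more often than genes elsewhere in inhibitory neurons (4 of 40 against 35 of 15099; Fisher's exact test, odds ratio 47.7, 95% interval 11.7 to 144) and in CA1 neurons (odds ratio 9.22), with odds ratios of 0.513 to 2.89 in the other 6 classes. Unc5c is 1 of the 4, so its fall may belong to the locus. Gm32754, named after its values were seen, is another, and rose in all 4 neuron classes (adjusted p = 1.53e-07 or less). The CA1 calls include Gbp7, also named afterwards, which was called in 6 classes, glia among them, and need not reflect the locus. Its call in CA1 neurons was lost without M_E4_P301S replicate 2 (adjusted p = 0.999), at a log2 change of 1.44, in a range of 2.38e-09 to 0.999 over 25 alternatives. Counts from the transgene and a genomic difference around the gene, such as the site of the transgene, may both hold, and no biological explanation was tested.

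Other splits were counted for the remaining results, as the real count of genes against the highest other. For P301S, 1 of 40 splits, the real one, reached the real count in 5 classes. It was 2641 against 267 in microglia, 2715 against 311 in astrocytes and 1006 against 230 in oligodendrocytes. In OPC it was 267 against 71 and in DG 1080 against 550. In CA1 neurons 2 of 40 reached it (258 against 450), in CA3 2 (127 against 588) and in inhibitory neurons 4 (40 against 1413). With 40 splits, unadjusted over classes, chance is not excluded in any. The splits with 588 and 1413 genes point to a structure of the samples whose cause was not tested. For APOE, 1 of 40 splits reached the real count in all 8 classes, at 251 against 1 in microglia, 906 against 0 in astrocytes, 833 against 0 in oligodendrocytes and 239 against 1 in OPC. The other 4 stood at 2182 against 1 (DG), 2202 against 1 (CA1), 1081 against 0 (CA3) and 2882 against 2 (inhibitory neurons). Chance stays open for the same reason, as does depth. For R47H in microglia 4 of 40 reached the real count (1 against 42), so chance is not excluded. Its 1 gene, Trem2, stood at 172 to 267 in R47H and 281 to 610 CPM in other P301S libraries. The highest other counts for R47H were 1 in astrocytes, 0 in oligodendrocytes, 1 in OPC, 1 in DG, 0 in CA1, 3 in CA3 and 1 in inhibitory neurons, where the real count was 0 and all 40 splits reached it.

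For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In microglia the real count and the highest other were 549 against 5 for P301S in APOE3 females, 404 against 1 in APOE4 females and 1741 against 116 in males. They were 0 against 1 for R47H in APOE3 females, 0 against 1 in APOE4 females and 28 against 7 in males. For APOE they were 0 against 3 in non-transgenic, 0 against 1 in P301S, 1 against 0 in P301S R47H females and 0 against 0 for mice with both risk alleles. Only the real split, 1 of 10, reached its count for P301S in the 3 strata, for R47H in males and for APOE in P301S R47H females, and all 10 reached the count of 0 in the other 5 results.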
